A study of Mus musculus with 6 samples.

How the data were processed

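The series holds 6 RNA sequencing libraries of total RNA from GC-1spg cells grown in DMEM with 10% FBS. Per the labels' protocols, the cells were transfected at 60% density with siRNA and collected after 48 h. The groups, si-NC and si-METTL3, and the replicate numbers 1 to 3 were taken from the sample titles. The labels print 1 sequence for both the METTL3 siRNA and the control siRNA, so the sequence of the control is not known, and they tag the control libraries as untreated although they received the control siRNA. None of the 6 libraries is of untransfected cells.

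The authors deposited an mRNA table of 22298 genes (4631 with 0 counts in every library) and a lncRNA table of 30924 transcripts (14930 with 0 counts). Per the file headers, each holds counts and FPKM values per library. Per the submitters' processing notes, fastp, Bowtie2, StringTie and RSEM were used with the mouse build mm9, with no versions and no roles given. Every count in the deposited tables was a whole number, and if RSEM made them the authors rounded its estimates. The deposited FPKM values are scaled to transcript length and library total, and their ratio to the counts showed that both tables were scaled to the same library total. The authors' group means equal the mean FPKM, with 0 written as 0.001, and their log2 fold change is the log2 ratio of these means. The deposited p-values and adjusted p-values come from a test that is not given in the sources used here. How reads shared between paralogs, overlapping genes or transcripts of 1 gene were divided, and whether strand was used, is not given either.

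At an adjusted p under 0.05 the authors' deposited table lists 2649 mRNA genes and 217 lncRNA transcripts. Of these, 2335 and 40 were also called here, all but 1 in the same direction. The mRNA identifiers are Ensembl genes, 22255 of which were found in GENCODE M21 (GRCm38). The lncRNA table gives 29916 Ensembl transcripts and 1008 assembled transcripts named MSTRG, with no gene name or position. GENCODE M21 held 29627 of its identifiers, and 14217 of these belonged to protein-coding genes. That annotation served for names, transcript lengths, GC content, 3′ UTRs, neighbours within 5000 bp and the position of the siRNA, and no coordinate was converted between builds.

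Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, the filterByExpr filter, a quasi-likelihood fit of the group without covariates, and Benjamini-Hochberg adjustment with a threshold of 0.05. The 2 tables were tested separately, and the lncRNA table at the level of transcripts since it names no genes. One assembled transcript, MSTRG.3770.1, took 22.9% to 35.3% of the lncRNA counts. Levels are counts scaled by edgeR's cpm (CPM) to the table's effective library size, given as mean ± SD over the 3 libraries of a group. The CPM of the lung, blood, brain and other tissue marker genes listed below are the exception. They were scaled to each library's total count in the mRNA table, without TMM factors. The macrophage and endothelial list kept the effective library size. SE is the log2 fold change divided by the square root of the F statistic. Of 49 gene lists fixed before the data were examined, 48 had at least 3 tested members in the mRNA table and were tested with camera of limma 3.58.1, two-sided, with a preset correlation of 0.01 between genes and again with an estimated correlation. The remaining list, of long noncoding RNAs, was described in the lncRNA table. The same test was run on the authors' ontology process and KEGG terms with 10 to 500 tested members. Share comparisons used Fisher's exact test in scipy 1.17.1. Figures were drawn with matplotlib 3.10.9.

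Genes were named by a rule fixed before the data were examined. It took Mettl3 and the m6A writers, erasers and readers, and the 12 largest rises and 12 largest falls among called genes with at least 5 CPM, no overlap between the groups and no predicted or clone name. Of the 8 lists with the smallest p it took the 4 leading members in the list's direction and 2 in the other, and of each further list the leading called member. For lncRNA it took the fixed list and the 5 largest changes each way above 1 CPM, at most 2 each way without a symbol, which gave 4 rises. Members named to spell out a count of 5 or fewer, members of annotation terms, and genes said to be so were chosen after their values were seen. Some genes that the rule or the text would name are left out of the text and figures.

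The tests were tried on simulated counts drawn from the means and library sizes of these libraries. In 12923 simulated mRNA genes, 16.9% of 1.5-fold, 69.7% of 2-fold and 92.3% of 4-fold changes were recovered, and 4.9% of the calls were false. In 5310 simulated lncRNA transcripts the recovered shares were 0%, 1.7% and 36.2%, so most changes were missed there, even at 4-fold. Floors for counts of 0 cover counting error only. Camera recovered 5 of 5 shifted lists and called 0 others, but the simulated genes were drawn independently of each other. False calls that correlation between genes can cause were therefore not measured.

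Alternatives chosen before the data were examined were other normalizations, filters and tools (DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1)), 1 surrogate variable from sva 3.50.0, the replicate number as a block, the joined tables, camera on ranks, and leaving out each library. Added after the data were seen were a correction of each library for transcript length and GC content and the summing of lncRNA transcripts per gene. Marker genes of lung, blood, brain, liver, heart and muscle, kidney, pancreas and gut, and testis germ cells, and genes with a 5′ terminal oligopyrimidine (TOP) motif that encode no ribosomal protein (20 tested), were listed after the data were seen.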

Results

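GC-1spg is an immortalised mouse cell line used as a model of type B spermatogonia. METTL3 is the catalytic subunit of the nuclear complex that writes N6-methyladenosine (m6A) into messenger RNA. The series set out to compare RNA levels between spermatogonial cells that differ in m6A. Its libraries measure RNA levels alone, so neither m6A nor METTL3 protein was measured here. RNA sequencing was carried out on 6 libraries of GC-1spg cells, 3 transfected with a control siRNA (si-NC) and 3 with an siRNA against Mettl3 (si-METTL3), collected 48 h after transfection. The mRNA table summed to 35701752, 29679593 and 37698956 counts in the si-NC libraries and to 31469144, 22146057 and 24714683 in the si-METTL3 libraries. The lncRNA table held 2743423, 2631377 and 3111037 counts in si-NC and 2536688, 1982088 and 2134684 in si-METTL3. The labels do not say whether the replicates came from separate cultures, so the p-values measure the spread between these 6 samples, which may be technical.

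Mettl3 (ENSMUSG00000022160), the targeted gene, lies on the minus strand of chromosome 14 (52294841 to 52305128, GRCm38). Its counts were 606, 578 and 683 in the si-NC libraries and 142, 134 and 136 in the si-METTL3 libraries. This corresponded to 18.4 ± 0.974 CPM (counts scaled to library size; SD, n = 3) in si-NC and 5.31 ± 0.785 in si-METTL3, a log2 fold change of -1.79 (SE 0.14, edgeR adjusted p = 0.000579). The fall kept its call when any 1 library was left out, with log2 fold changes between -1.88 and -1.70. The siRNA sequence in the labels, GCTACCGTATGGGACATTA, matched coding exon 6 of Mettl3 transcript ENSMUST00000022767 (chromosome 14, 52297548 to 52297566, GRCm38). No other annotated gene held an unbroken run of 16 of its 19 bases. Matches with a mismatch inside were not searched for.

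**Figure D1:**
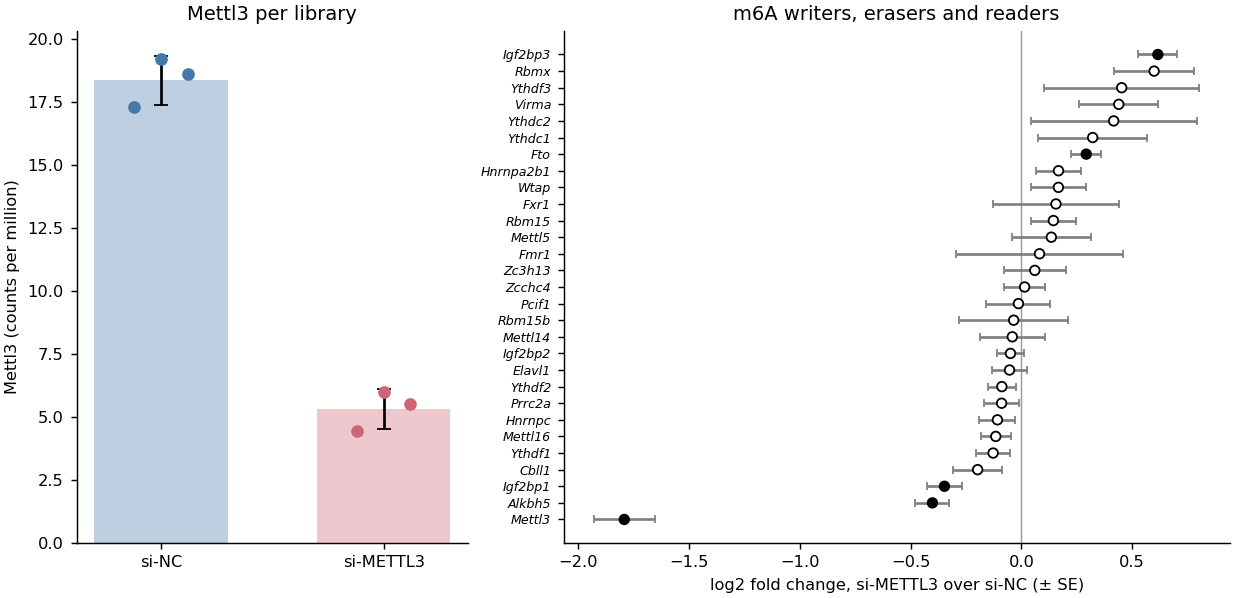
Left, Mettl3 in CPM per library (points), with group means (bars) and SD (whiskers, n = 3); the si-METTL3 libraries average 5.31 against 18.4 in si-NC. Right, log2 fold change (± SE) of the tested m6A writers, erasers and readers, with filled points for genes past an adjusted p of 0.05; Mettl3 lies lowest at -1.79.

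Of the 12 tested m6A writers and writer subunits only Mettl3 passed the threshold, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.602; its median was 0.001 and its mean -0.10). Mettl14, the partner of METTL3 in the catalytic core, had a log2 fold change of -0.04 (SE 0.15), and the adaptor Wtap 0.17 (SE 0.12). The values of Virma (0.44, SE 0.18), Rbm15 (0.14), Zc3h13 (0.06), Rbm15b (-0.03) and Cbll1 (-0.20) did not pass either, nor did those of the methyltransferase genes Mettl16 (-0.12), Mettl5 (0.14), Zcchc4 (0.01) and Pcif1 (-0.01). Among 17 erasers and readers, 2 rose and 2 fell, and 3 and 2 did so when adjusted over the list alone (list adjusted p = 0.886). The eraser Fto rose (log2 fold change 0.29, adjusted p = 0.0261) and the eraser Alkbh5 fell (-0.40, adjusted p = 0.0155). The reader Igf2bp3 rose (0.62, adjusted p = 0.00619) and its relative Igf2bp1 fell (-0.35, adjusted p = 0.0257). The calls of Fto, Igf2bp1 and Alkbh5 held in 1, 2 and 3 of the 6 fits that left out a library, with edgeR adjusted p up to 0.12, 0.109 and 0.0778, and that of Igf2bp3 in 6. No change was detected in the YTH-domain readers Ythdf1 (-0.13), Ythdf2 (-0.09), Ythdf3 (0.45), Ythdc1 (0.32) and Ythdc2 (0.42), in Igf2bp2 (-0.05), Elavl1 (-0.05), Fmr1 (0.08), Fxr1 (0.16), Prrc2a (-0.09), Hnrnpc (-0.11) or Hnrnpa2b1 (0.17). Rbmx (0.60, SE 0.18) passed only when adjusted over the list alone.

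Across the transcriptome, 2468 of 13082 tested mRNA genes differed between si-METTL3 and si-NC, 1134 of them higher and 1334 lower in si-METTL3 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). A change of at least 2-fold was reached by 199 of the higher and 181 of the lower genes. The number of calls depended on single libraries. It was 4917 without si-NC replicate 2, 1624 without si-NC replicate 3, 1356 without si-METTL3 replicate 1, 752 without si-NC replicate 1, 687 without si-METTL3 replicate 2 and 665 without si-METTL3 replicate 3. Of the 2468 genes, 578 were called in all 6 of these fits, 267 higher and 311 lower.

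The largest falls were in genes of the antiviral interferon response, and they were 15- to 29-fold over all 6 libraries. Without si-METTL3 replicate 2, Zbp1 reached -5.44 and Ifi44 -4.94 on the log2 scale. Zbp1, a sensor of Z-form nucleic acid, fell from 22.9 ± 5.33 to 0.837 ± 0.559 CPM (SD, n = 3; log2 fold change -4.83, SE 0.44, edgeR adjusted p = 0.00119). Usp18, which removes ISG15 from proteins, fell from 101.03 ± 14.1 to 4.31 ± 0.755 (-4.55, SE 0.17, edgeR adjusted p = 5.42e-05). The dynamin-like GTPase Mx2 fell from 119 ± 8.45 to 6.59 ± 0.778 (-4.17, SE 0.12, edgeR adjusted p = 3.77e-05). The others among the 12 were the 2′-5′-oligoadenylate synthetases Oas1a (-4.35), Oas2 (-4.34) and Oas1g (-3.93), the IFIT genes Ifit3b (-4.55) and Ifit3 (-4.28), Trim30a (-4.11), Ifi44 (-4.01), Cmpk2 (-3.96) and the GTPase gene Tgtp2 (-3.90). Oas1a and Oas1g, and Ifit3 and Ifit3b, are close paralogs whose reads the counting could have split, so each member's own level is uncertain.

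In the list of interferon-stimulated genes, 42 of 44 tested members fell and none rose, with the same counts adjusted over the list alone. The median log2 fold change was -2.80, and this was the only list whose camera call held with an estimated correlation (adjusted p = 2.08e-190 with the preset correlation, adjusted p = 0.0211 with an estimated correlation). Besides those above, Oas3 fell by 3.80 and Oas1b by 2.90 on the log2 scale. Genes of the signalling core, chosen after their values were seen, fell as well: Irf7 (-3.38), Isg15 (-3.70), Irf9 (-1.57), Stat2 (-1.44) and the RNA sensor Ddx58 (-1.85). The members that did not pass were Eif2ak2 (-0.37, SE 0.34) and Ifit2 (-0.01, SE 0.32). The interferon genes themselves were close to undetected: 15 of 21 listed had 0 counts in every library, and Ifnb1 had 15, 6 and 12 counts in si-NC and 6, 4 and 3 in si-METTL3, too few to be tested.

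**Figure D2:**
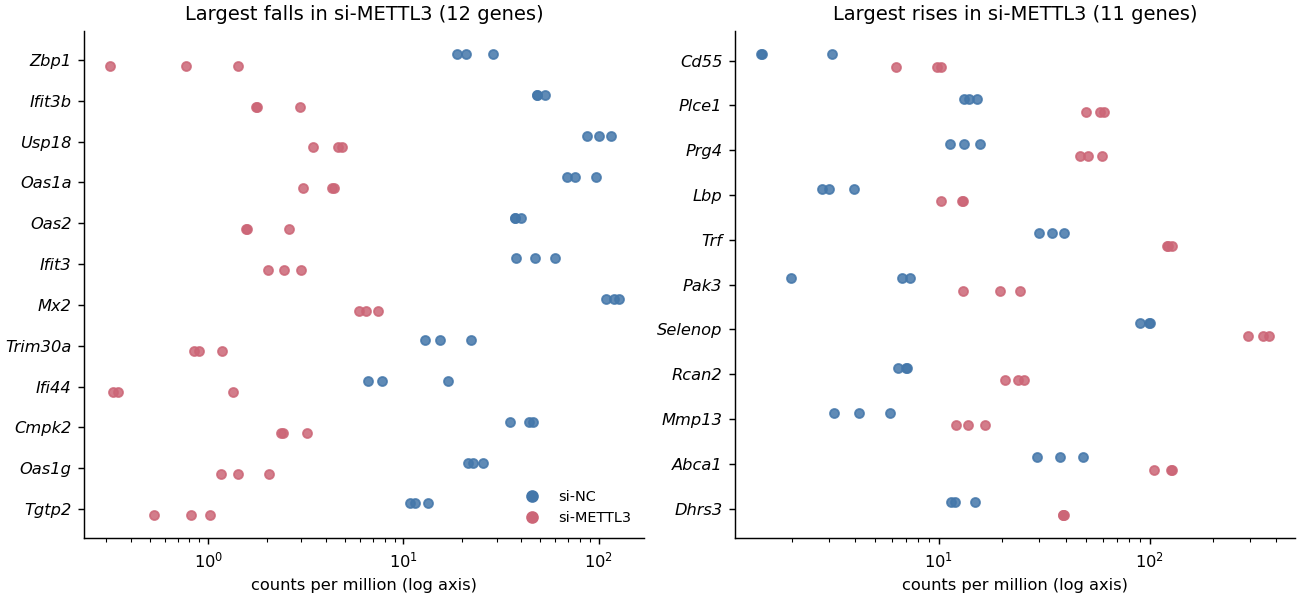
CPM (log axis) per library of the 12 genes with the largest falls and of 11 with the largest rises; each point is 1 library, blue for si-NC and red for si-METTL3. The groups do not overlap for any gene shown, which was a condition of their selection; Zbp1 averages 22.9 in si-NC and 0.837 in si-METTL3.

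The largest rises reported were 3.06- to 4.41-fold and covered genes of varied function. Cd55, which encodes a complement regulator, rose from 2.00 ± 0.972 to 8.78 ± 2.20 CPM (SD, n = 3; log2 fold change 2.14, SE 0.36, edgeR adjusted p = 0.0102). The phospholipase gene Plce1 rose from 14.1 ± 1.08 to 56.1 ± 5.55 (1.99, SE 0.11, edgeR adjusted p = 0.000136). Selenop, which encodes the selenium transport protein of plasma, rose from 96.6 ± 5.69 to 335 ± 39.0 (1.80, SE 0.10), and Trf, encoding transferrin, from 34.5 ± 4.66 to 124 ± 3.28 (1.84, SE 0.11). Prg4 (1.96), Lbp (1.88), Pak3 (1.83), Rcan2 (1.77), the collagenase gene Mmp13 (1.68), the cholesterol transporter gene Abca1 (1.64) and Dhrs3 (1.61) were the others. The calls of these genes held in every fit that left out a library, except that of Pak3, which held in 3 of 6 (edgeR adjusted p up to 0.122).

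Of 48 gene lists tested, 17 passed the threshold with camera's preset correlation, 12 downward and 5 upward. With an estimated correlation the 16 others lost their call, at adjusted p between 0.619 and 0.776. Inflammatory genes fell alongside the interferon-stimulated ones. In the list of NF-kB targets and chemokines, 12 of 24 members fell and none rose, while adjusted over the list alone 17 fell and 1 rose (median -0.53, adjusted p = 3.33e-11, adjusted p = 0.619 with an estimated correlation). The chemokine genes Ccl5 (-2.28), Cxcl10 (-1.91) and Ccl2 (-1.08) and the macrophage growth factor gene Csf1 (-1.06) led the list. Ccl5 and Cxcl10 are also known to respond to interferon.

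Genes of the integrated stress response under ATF4 were lower, with 17 of 37 falling and 2 rising, and 25 and 3 adjusted over the list alone (median -0.34, adjusted p = 3.69e-08, adjusted p = 0.628 with an estimated correlation). Slc3a2, a subunit of amino acid transporters, fell by 0.97 on the log2 scale, the transcription factor gene Ddit3 by 1.14, the pseudokinase gene Trib3 by 0.93 and Sesn2 by 0.86. Ddit4 (0.43) and the mitochondrial folate enzyme gene Aldh1l2 (0.47) rose. Of 20 YAP and TEAD targets, 9 fell and 3 rose, with the same counts adjusted over the list alone (adjusted p = 0.00484, adjusted p = 0.619 with an estimated correlation), and Gadd45b (-1.22), Ccn1 (-0.83), Ccn2 (-0.80) and Ankrd1 (-0.71) were among those lower, whereas Dock5 (0.52) and Myof (0.35) were higher. Of 24 immediate early genes, 9 fell and 2 rose, and 11 and 2 adjusted over the list alone (adjusted p = 0.00543, adjusted p = 0.744 with an estimated correlation), Myc by 0.67 on the log2 scale. The call of the YAP and TEAD list was lost when camera ran on ranks (adjusted p = 0.0642). Of 15 MAPK feedback genes, 5 fell, and 7 adjusted over the list alone. Fosl1 fell 2.55-fold (list adjusted p = 0.0296, adjusted p = 0.744 with an estimated correlation).

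RNA levels of the protein synthesis machinery were lower by smaller amounts. For ribosomal proteins the amount shrank after the length and GC correction given below. Of 78 genes in the list of cytosolic ribosomal proteins, 44 fell and none rose, and 65 fell adjusted over the list alone (median -0.38, adjusted p = 8.3e-17, adjusted p = 0.744 with an estimated correlation). Rpl12 fell from 164 ± 11.4 to 78.2 ± 7.16 CPM (SD, n = 3; log2 fold change -1.07, edgeR adjusted p = 0.000966), Rpl21 by 0.78 on the log2 scale and Rpl10a by 0.55. Rps19bp1, also counted in the list, binds a ribosomal protein and is not one itself (-0.71). Of 38 ribosome biogenesis factors, 12 fell and none rose, and 16 fell adjusted over the list alone (median -0.27, adjusted p = 5.78e-05, adjusted p = 0.619 with an estimated correlation), among them Rrs1 (-0.64), Rrp9 (-0.66), Pes1 (-0.57) and Utp15 (-0.39). Of 36 spliceosome genes, 9 fell and 13 did so adjusted over the list alone, Snrpd1 by 0.42 (adjusted p = 0.0103, adjusted p = 0.744 with an estimated correlation).

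Of 58 genes of mitochondrial complexes I and IV, 8 fell and none rose, and 7 fell adjusted over the list alone (median -0.20, adjusted p = 0.000874, adjusted p = 0.776 with an estimated correlation), including Ndufs3 (-0.70), Ndufs7 (-0.55), Ndufa6 (-0.45) and Ndufa10 (-0.40). Of 38 proteasome genes, 8 fell and none rose, and 9 fell adjusted over the list alone (median -0.18, adjusted p = 0.00186, adjusted p = 0.744 with an estimated correlation). The largest of these was in Psmb10 (-1.28), an interferon-inducible subunit of the immunoproteasome, followed by Psmb3 (-0.52), Psma4 (-0.43) and Psmd6 (-0.34). Libraries differed in how expression depended on transcript length, with slopes per doubling of length of -0.10, 0.04 and -0.17 on the log2 scale in si-NC and 0.02, 0.09 and 0.12 in si-METTL3. With each library corrected for length and GC content, an alternative added after the data were seen, the medians were -0.15 for ribosomal proteins (adjusted p = 3.51e-05), -0.01 for complexes I and IV (adjusted p = 0.721), -0.02 for the proteasome (adjusted p = 0.429) and -0.16 for the spliceosome (adjusted p = 0.0712).

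Of 13 mitochondrially encoded genes, 2 rose, mt-Nd4l (0.91) and mt-Nd3 (0.65), and 6 rose adjusted over the list alone (median 0.55, adjusted p = 0.0169, adjusted p = 0.744 with an estimated correlation). The call was lost without si-NC replicate 3 (adjusted p = 0.0643). Extracellular matrix genes went both ways, with 13 of 51 higher and 6 lower, and 18 and 6 adjusted over the list alone (median 0.23, adjusted p = 0.00484, adjusted p = 0.744 with an estimated correlation). Col6a1, a chain of collagen VI, rose from 154 ± 10.1 to 307 ± 10.4 CPM (SD, n = 3; log2 fold change 0.99, edgeR adjusted p = 0.000504). Of the list members named so far, the calls of Ddit4, Aldh1l2, Utp15, Ndufs7, Ndufa10, Ndufa6, Psmb3, Psma4, Psmd6, Myof, Stat2, mt-Nd3 and mt-Nd4l held in at most 4 of the 6 fits that left out a library. The extracellular matrix list's call was lost after the length and GC correction (adjusted p = 0.248) and without si-NC replicate 2 (adjusted p = 0.0646).

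**Figure D3:**
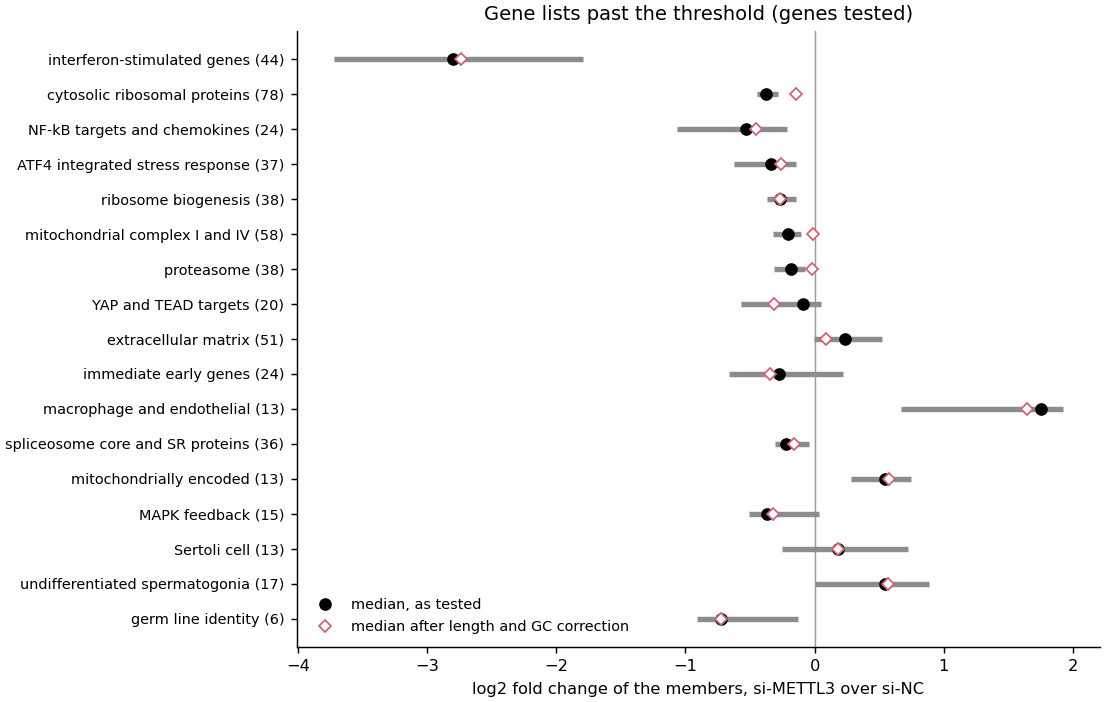
Median log2 fold change (black points) and interquartile range (grey bars) of the members of each gene list past the threshold, with the number of genes tested in parentheses; open diamonds are medians after correction of each library for transcript length and GC content. Interferon-stimulated genes lie at -2.80, and the medians of complexes I and IV and of the proteasome move to -0.01 and -0.02 after the correction.

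Markers of spermatogenic stages were few and mostly low. Only 6 of 23 germ line identity genes and 17 of 29 markers of undifferentiated spermatogonia had enough counts to be tested. For differentiating spermatogonia, meiotic prophase and spermatids the tested markers were 7 of 16, 10 of 33 and 4 of 26. Of 17 tested markers of undifferentiated spermatogonia, 4 rose, Tspan8 (0.88), Itga6 (0.59), Bcl6b (0.97) and Gfra1 (0.65), the last being the receptor subunit for GDNF (adjusted p = 0.0325, adjusted p = 0.619 with an estimated correlation). Adjusted over the list alone, 4 rose and 1 fell. The call was lost without si-NC replicate 2 (adjusted p = 0.148) and without si-METTL3 replicate 1 (adjusted p = 0.0608). Of 6 germ line identity genes, 2 fell, also adjusted over the list alone, Tdrd7 (-1.23) and the PIWI gene Piwil2 (-0.74; adjusted p = 0.0391, adjusted p = 0.619 with an estimated correlation). This call was lost without si-NC replicate 2 (adjusted p = 0.34), si-NC replicate 3 (0.108), si-METTL3 replicate 2 (0.0643) or si-METTL3 replicate 3 (0.218), on ranks (0.0642) and after the length and GC correction (0.0876). Of 13 Sertoli cell markers, Trf (1.84), Clu (1.37) and Wt1 (0.61) rose and Gdnf (-0.55) and Gata4 (-0.41) fell, with 4 higher and 2 lower adjusted over the list alone (adjusted p = 0.0306, adjusted p = 0.619 with an estimated correlation, adjusted p = 0.474 on ranks). None of the 10 meiotic prophase or 4 spermatid markers tested passed, and 1 of 7 markers of differentiating spermatogonia did (Dnmt3a, 0.29, edgeR adjusted p = 0.0343), with the same counts adjusted over each list alone (list adjusted p = 0.871, 0.955 and 0.76). Of these markers the calls of Gfra1, Gata4 and Dnmt3a held in 1 of the 6 fits that left out a library, and that of Piwil2 in 3. The Dnmt3a value changed sign after the length and GC correction (-0.0555, edgeR adjusted p = 0.772).

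Markers of another tissue moved with part of the libraries. Summed over 19 lung genes such as Sftpc and Scgb1a1, the level was 3.92 and 2.43 CPM in si-NC replicates 1 and 2, 78.7 in si-NC replicate 3, and 123, 122 and 82.6 in the si-METTL3 libraries. Haemoglobin and other blood genes followed the same pattern, with 16, 24 and 443 summed counts in si-NC and 600, 356 and 306 in si-METTL3, and 21 brain genes summed to 11.5, 32.0 and 31.8 CPM in si-NC and 43.6, 46.6 and 38.4 in si-METTL3. Of 18 tested brain genes 1 passed, the synaptic vesicle gene Syt1 (1.28, edgeR adjusted p = 0.023), and none did without si-METTL3 replicate 1, 2 or 3. None of 18 tested lung genes passed edgeR's threshold over all 6 libraries (1 with DESeq2, 9 with limma-voom), whereas 19 of 19 did without si-NC replicate 3. With 1 surrogate variable 13 of 18 lung and 4 of 4 blood genes passed. Limma on log2(FPKM + 1) called 2 of 10 lung genes, or 4 of 19 with no filter, and the length and GC correction 1 of 18. The 13 tested macrophage and endothelial markers summed to 29.5 and 29.1 CPM in si-NC replicates 1 and 2, 54.4 in si-NC replicate 3 and 67.3, 66.0 and 54.8 in si-METTL3. The list had a median log2 fold change of 1.75 with no member past the threshold, nor adjusted over the list alone (adjusted p = 0.00874, adjusted p = 0.744 with an estimated correlation, adjusted p = 0.0712 without si-NC replicate 2).

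**Figure D4:**
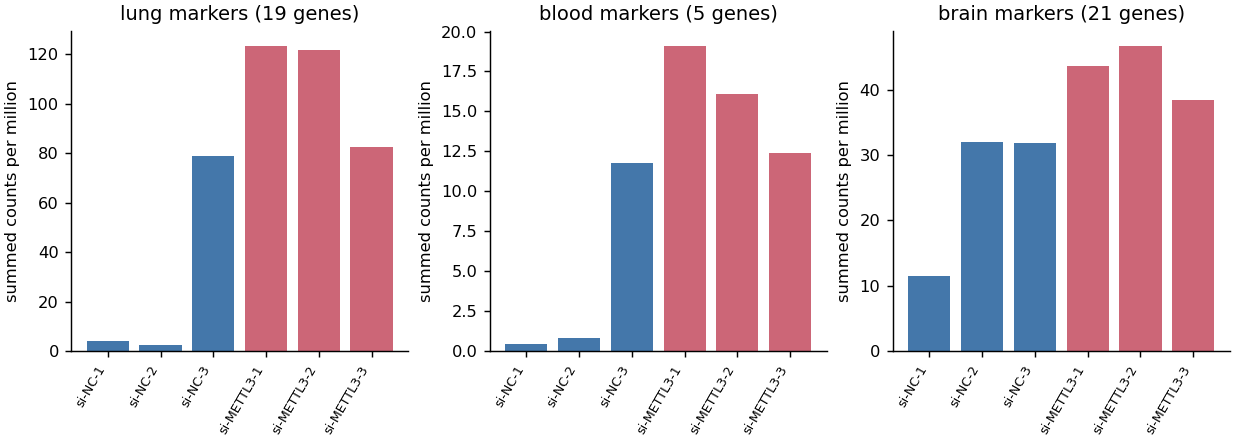
Summed CPM, scaled to library totals without TMM factors, of lung, blood and brain marker genes in each library (bars, blue for si-NC and red for si-METTL3). Lung markers are at 3.92 and 2.43 in si-NC replicates 1 and 2 and at 78.7 or above in the other libraries.

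The remaining lists did not pass over all 6 libraries with the preset correlation. In the cell cycle lists, 2 of 43 G1/S and replication genes rose and 3 fell, and 1 of 42 G2/M genes rose and 5 fell (2 and 3, and 1 and 4, adjusted over the list alone), with adjusted p = 0.666 and 0.76. The G2/M list had a median of 0.05 and a mean of 0.06 although its test pointed downward. Ccne1 of the G1/S list rose by 0.86 on the log2 scale and Prc1 of the G2/M list fell by 0.57. Of 15 D-type cyclins and CDK inhibitors, 3 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.886). The member that fell was Ccnd1, encoding cyclin D1, from 274 ± 28.9 to 143 ± 7.19 CPM (SD, n = 3; log2 fold change -0.94, edgeR adjusted p = 0.00176). Of 36 p53 targets, 9 fell and 2 rose, and 10 and 2 adjusted over the list alone (adjusted p = 0.0723, adjusted p = 0.0489 without si-NC replicate 3, 0.0457 without si-METTL3 replicate 2 and 0.0487 without si-METTL3 replicate 3), led by Tap1 (-2.12), a peptide transporter gene that also responds to interferon. Of 25 genes of the unfolded protein response, 7 rose and none fell, and 8 and 3 adjusted over the list alone (adjusted p = 0.0917, adjusted p = 0.00794 after the length and GC correction and 0.0484 on ranks), including the chaperone gene Hspa5 (0.37). Cyp51 (-0.77) led 5 of 24 cholesterol synthesis genes that fell, 6 adjusted over the list alone (adjusted p = 0.0943, adjusted p = 0.044 on ranks). Of 14 peritubular myoid and fibroblast markers, 3 rose, Pdgfra (0.78) among them, and 1 fell, and 4 and 1 adjusted over the list alone (adjusted p = 0.068, adjusted p = 0.0159 without si-NC replicate 3, 0.0196 without si-METTL3 replicate 3 and 0.024 on ranks). Of 64 replication-dependent histone genes, 7 fell, H4c4 (-0.48) among them, and 0 passed adjusted over the list alone (adjusted p = 0.11, adjusted p = 0.0407 without si-NC replicate 1, 0.039 without si-NC replicate 2, 0.0372 without si-METTL3 replicate 1 and 0.024 on ranks). After the length and GC correction the histone list pointed upward, from a median of -0.09 to 0.13 (adjusted p = 0.0972). The calls of Hspa5 and H4c4 held in 3 of the 6 fits that left out a library.

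Among the ontology and pathway terms of the authors' annotation, 172 of 2472 passed, 85 upward and 87 downward, and none with an estimated correlation (smallest adjusted p = 0.671, with 86 terms at an unadjusted p under 0.05). The smallest p was for negative regulation of viral genome replication (17 of 31 genes lower, none higher, adjusted p = 1.19e-56). Cellular response to interferon-beta (24 of 37 lower), the KEGG ribosome pathway (62 of 131 lower) and rRNA processing (51 of 134 lower) followed the lists above. Upward terms were led by phospholipase C-activating receptor signalling (6 of 15 higher, adjusted p = 2e-05) and by axon guidance (37 of 155 higher and 6 lower, adjusted p = 0.000159). Summed brain markers were also higher in each si-METTL3 library (38.4 to 46.6 CPM) than in each si-NC library (11.5, 32.0 and 31.8 CPM). In si-NC replicate 1 alone, 9 of the 21 brain genes lay at least 5 times below every other library. The axon guidance call was lost after the length and GC correction (adjusted p = 0.0565). With that correction 79 terms passed, 71 of them among the 172, and 113 terms passed without si-NC replicate 2.

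In the lncRNA table, 42 of 5728 tested transcripts passed, 9 higher and 33 lower in si-METTL3 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 15 were transcripts assembled by the authors, 11 belonged to noncoding genes, 12 were noncoding transcripts of protein-coding genes, 2 (of Oas1b and Mx2) were noncoding transcripts of genes annotated as polymorphic pseudogenes, and 2 had identifiers that did not match the annotation used here. None of the 42 held in all 6 fits that left out a library, which called 77 transcripts without si-NC replicate 2, 2 without si-NC replicate 1 or si-METTL3 replicate 1, and 0 without any other (668 to 715 at an unadjusted p under 0.05).

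Of 102 tested transcripts of the fixed list of long noncoding RNAs, 6 fell and none rose, and 14 fell and none rose adjusted over the list alone. All 6 came from host genes of small nucleolar RNAs (snoRNAs), and each call held in 1 of the 6 fits that left out a library. Snhg1 (ENSMUST00000206155) fell from 3560 ± 464 to 1155 ± 22.7 CPM of the lncRNA table (SD, n = 3; log2 fold change -1.62, SE 0.14, edgeR adjusted p = 0.00913). The others were Snhg12 (-1.87), Snhg15 (-1.64), Zfas1 (-1.64), Snhg17 (-1.15) and Gas5 (-0.93). With transcripts summed per gene, a step added after the data were seen, 5 of 15 snoRNA host genes fell and none rose (Snhg1, Zfas1, Snhg15, Snhg12 and Gas5), and 0 of the 19 other genes of the list passed edgeR's test (1 at an unadjusted p under 0.05). This grouping was made after the values were seen and was not tested on other data. The abundant nuclear RNAs Malat1 (0.42, SE 0.29) and Neat1 (0.36, SE 0.16), summed per gene, did not pass.

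**Figure D5:**
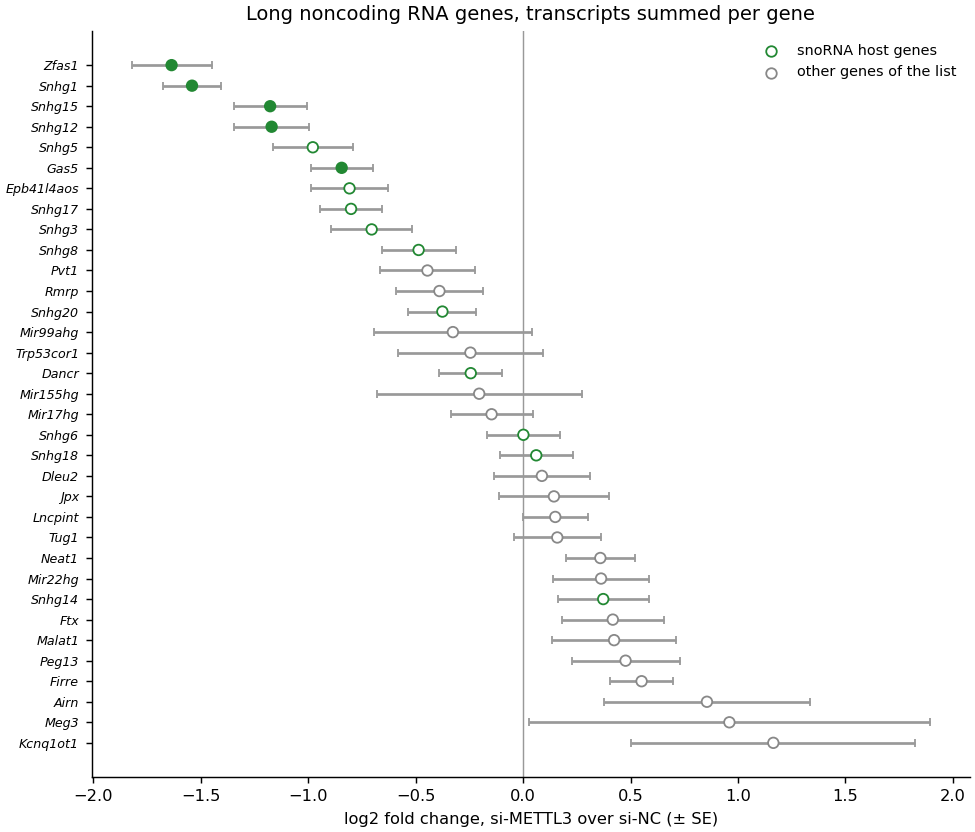
Log2 fold change (± SE) of the genes in the long noncoding list, transcripts summed per gene; green points are snoRNA host genes, grey points the other genes, and filled points passed an adjusted p of 0.05. The 5 filled points are Snhg1, Zfas1, Snhg15, Snhg12 and Gas5.

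The largest falls among called lncRNA transcripts with at least 1 CPM included noncoding transcripts of Oas1b (ENSMUST00000182725, -3.90, SE 0.27) and Mx2 (ENSMUST00000190097, -4.35, SE 0.69, and -5.05 without si-METTL3 replicate 3). The assembled transcripts MSTRG.14681.1 (-4.15) and MSTRG.2350.1 (-3.71) were others. These falls rest on low si-METTL3 counts, 10, 11 and 14 for Oas1b and 2, 0 and 3 for Mx2. MSTRG.14681.1 had 4, 1 and 4 counts there, and MSTRG.2350.1 had 4 in every si-METTL3 library. A Myo19 transcript (ENSMUST00000141173) had 52, 70 and 172 counts in si-NC and 0 in every si-METTL3 library, at least 26.4-fold lower (at least 16.5-fold without si-NC replicate 3), and an Mrm3 transcript (ENSMUST00000155526) had 0 in every si-NC library and 31, 31 and 15 in si-METTL3, at least 10.6-fold higher, each against a floor of 3 counts per library. The rises included Gm20186 (1.22), MSTRG.1991.1 (1.27) and MSTRG.12504.1 (1.97). Of the 12 called noncoding transcripts of a gene also present in the mRNA table, 9 had a called mRNA gene, against 21.1% of the uncalled (Fisher's exact test, two-sided, p = 9.98e-05). Of the 12, 91.7% moved in the direction of the gene, against 67.0% of the uncalled (Fisher's exact test, two-sided, p = 0.119). At an unadjusted p under 0.05 these shares were 86.4% and 64.4% (Fisher's exact test, two-sided, p = 2.14e-21). Transcripts that share 1 gene, such as the called ones of Ddx58, were counted as separate pairs in every such test. The pairs are therefore not independent, and the p-values of these tests can be too small. Reads shared between such transcripts and their gene cannot be told apart here. For lncRNA transcripts that overlapped or neighboured another gene within 5000 bp, 4 of 10 called transcripts (40.0%) had a called neighbour, against 19.5% of the uncalled (Fisher's exact test, two-sided, p = 0.115). Of the 10, 60.0% moved in the direction of the neighbour, against 57.6% of the uncalled.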

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

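The length and GC correction and the summing per gene were chosen after the data were seen. The log2 fold change of Mettl3 kept its call under every alternative, between -1.88 and -1.48. The count of mRNA genes stayed within 1.5 times of 2468 under other normalizations, filters, DESeq2, limma-voom and FPKM values, and was 5588 with 1 surrogate variable, 3805 after the length and GC correction, and 665 to 4917 with 1 library left out. The count of 42 lncRNA transcripts was 150 with no filter, 79 with a stricter filter, 260 with DESeq2, 150 and 115 on log2(FPKM + 1) and log2(FPKM + 0.1), 25 on FPKM with no filter, 71 with 1 surrogate variable, 114 with the tables joined, and 0 to 77 with 1 library left out. The 17 gene lists became 1 with an estimated correlation, and the 172 terms became 0 with an estimated correlation, 79 after the length and GC correction, and 113 to 206 with 1 library left out. The share of called neighbouring lncRNA transcripts with a called gene was 46.8% at an unadjusted p under 0.05, against 33.5% of the uncalled (Fisher's exact test, p = 0.00466). The shares that moved in the neighbour's direction were 61.3% and 57.0% (Fisher's exact test, p = 0.381). Over all alternatives the named mRNA genes gave 2123 values on the same side of the threshold, 119 calls lost and 18 gained, and Dnmt3a alone reversed, to -0.0555 after the length and GC correction. The cause was not tested.

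No pairing by replicate number was detected. Deviations of libraries with the same number correlated at 0.07, 0.20 and -0.31 in the mRNA table and 0.05, 0.03 and -0.06 in the lncRNA table. Libraries with unlike numbers spanned -0.40 to 0.34 and -0.13 to 0.10. So few values cannot show that a number marks no shared batch. With the replicate block, edgeR called 1273 mRNA genes and 0 lncRNA transcripts (789 at an unadjusted p under 0.05, 260 with DESeq2 without the block). For the mRNA table, transcripts in place of genes were not run, since it holds genes alone. The lncRNA table was tested as transcripts, and 53 genes passed with transcripts summed per gene.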

Other observations

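The tests of the control siRNA, of the lung genes and of the length trend in complexes I and IV and the proteasome were chosen only after the results were seen, and the length and GC correction itself was added after the data were seen. The annotation terms described next were picked after their values were seen. Of 33 tested genes of semaphorin and plexin signalling, 12 rose and none fell, among them Plxna2 (log2 fold change 0.87), Plxna4 (1.10), Sema6d (1.13) and Sema4c (1.08; camera adjusted p = 0.000674, adjusted p = 0.926 with an estimated correlation, 0.139 after the length and GC correction). Brain markers summed to 38.4 to 46.6 CPM in the si-METTL3 libraries and to 11.5, 32.0 and 31.8 CPM in the si-NC libraries, lowest in replicate 1. Of 15 genes of the classical complement pathway, 6 rose and 1 fell, with C3 at 1.27, C9 at 2.18, C1s2 at 1.25 and C2 at -0.49, of which C3 alone kept its call in all 6 fits that left out a library (adjusted p = 0.00349, adjusted p = 0.926 with an estimated correlation). Lung markers summed to 3.92, 2.43 and 78.7 CPM in si-NC and 123, 122 and 82.6 in si-METTL3, and macrophage and endothelial markers to 29.5, 29.1 and 54.4 and to 67.3, 66.0 and 54.8. Of 12 genes of sialylation, 6 rose and none fell, with St8sia1 at 2.21 and St6gal1 at 0.60 (adjusted p = 0.00378, adjusted p = 0.926 with an estimated correlation). Of 13 genes of antigen presentation via MHC class Ib, 9 fell and none rose (adjusted p = 1.72e-07, adjusted p = 0.926 with an estimated correlation). Values of single class I histocompatibility genes were H2-Q4 at -1.43, H2-D1 at -1.41, H2-T23 at -1.25 and H2-K1 at -0.79, although these paralogs can share reads and the call of H2-K1 held in 3 of the 6 fits that left out a library.

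Interferon-stimulated genes had a median log2 fold change of -2.80. A seed match of the METTL3 siRNA in their own 3′ UTRs does not account for the fall of most of these genes. The 7-base site GGACATT, complementary to bases 2 to 8 of the strand that pairs with Mettl3, was present in 4 of the 42 members that fell (9.52%, exact 95% interval 2.66 to 22.6), against 11.3% of other genes (Fisher's exact test, p = 1.0). Stat2, of the signalling core, was 1 of the 4, and whether other members fell through it was not tested. Whether the interferon-stimulated genes were raised by the control siRNA or lowered with Mettl3 cannot be told apart. Of the 6 libraries, 0 came from untransfected cells, and the control's sequence is not known. A biological link to Mettl3 stays an open hypothesis.

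Across all genes, the same 7-base site went with lower levels in si-METTL3. Among 11760 genes searched, the 1328 with the site lay lower by a log2 shift of -0.10 (SE 0.0139) in a regression on 3′ UTR length, UTR GC content, transcript length and transcript GC content. Only 0.159% of the 630 rearrangements of its bases, the real one alone, gave as low a t value, and this also held in each of the 6 fits that left out a library. Without the regression the difference had the opposite sign, with medians of 0.03 with and 0.01 without the site, and the site of the other strand gave a shift of 0.0002 (SE 0.0324). The longer 8-base site, in 219 genes, gave a shift of -0.08 (SE 0.0316), no larger than that of the 7-base site, although seed pairing would predict a larger one. The rearrangements test the sequence itself, so they cannot tell seed pairing from another effect of lower Mettl3 at the same bases. Part of the smaller falls may still come from seed pairing of the siRNA to other transcripts, a candidate explanation that a second siRNA could test.

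Lung genes in 4 of the 6 libraries kept 1 ratio to each other, with a lowest pairwise correlation of log counts of 0.975 over 19 markers, which is consistent with RNA or reads of lung tissue in those libraries. The knockdown itself does not account for them, since si-NC replicate 3 lay 20.1 times above the next si-NC library. Sftpc, the most abundant, had 38, 1 and 1131 counts in si-NC and 1503, 1065 and 790 in si-METTL3. Of the 19, only Ager reached 1 CPM in both si-NC replicates 1 and 2, so the cells may express it. None of the 19 is in another gene list. The pattern reached beyond them: 53 genes lay at least 5 times lower in si-NC replicates 1 and 2 than in every other library. Lung markers made up 14 of the 53, and any other pair of libraries gave 3 to 9 genes. Over all 6 libraries 1 of 47 tested genes of the pattern was called, and 47 of 51 without si-NC replicate 3. Liver, heart and muscle, kidney, pancreas and gut, and testis germ cell markers summed to at most 5.06, 3.05, 0.607, 3.20 and 0.404 CPM. The germ cell markers were thus close to undetected, although the line is used as a model of spermatogonia. Ddx4 had 3, 7 and 2 counts in si-NC and 4, 1 and 7 in si-METTL3.

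After the length and GC correction the medians of complexes I and IV and of the proteasome lay at -0.01 and -0.019, so the trend could account for both calls. The trend was fitted to these same libraries, so the correction would also remove a real change that follows length or GC content. For these lists the 2 explanations cannot be told apart. For ribosomal proteins the corrected median of -0.146 lay between the bounds set before it was computed, and how much of the fall the trend explains cannot be told apart. The 20 other 5′ TOP transcripts had a median of -0.246 (camera p = 0.00105, p = 0.255 with an estimated correlation) and of -0.08 after the correction (p = 0.0336), so a lower level of 5′ TOP transcripts as a class stays open.

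The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave the largest result in each case (1 of 10 splits): 2468 mRNA genes against at most 721 in another split, 42 lncRNA transcripts against 0, 17 gene lists against 10 and 172 terms against 148. The split with 721 genes set si-NC replicates 1 and 3 and si-METTL3 replicate 1 against the rest, which follows the length trend. The other mixed splits called 0 or 1 mRNA genes, yet 4 to 10 lists and 6 to 148 terms passed there with the preset correlation. A count of lists or terms past the threshold therefore does not by itself mark the real groups.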
